A study of Homo sapiens with 4 samples.

How the data were processed

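GRO-seq libraries of U2OS cells with an inducible Myc vector were compared, 2 from mock-treated control cells and 2 from cells induced for 5 hours. Per the labels' protocols, induction used doxycycline, the nuclear run-on used bromo-UTP and the RNA was then fragmented. The labels do not say whether mock-treated cells also received doxycycline, so an effect of the drug itself is not separated from that of Myc. Labelled transcripts were captured with antibody-coated beads and libraries were made with a small RNA kit. Groups and replicate numbers came from the sample titles and source names. The deposited values are a signal per Ensembl gene, made by the authors from read counts that were quantile-normalised and floored, in 1 table for each replicate number that holds a control and a Myc-induced library. The submitters' processing notes name Bowtie2, HTSeq and the genome build hg19. Their versions and settings, the gene annotation and whether counting used strand are not given in the sources used here. Overlapping and antisense genes can therefore share reads, and so can near-identical copies of a gene.

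The unit was checked on the values. In each table both columns held the same sorted values, all of them whole numbers or halfway between whole numbers (100% of values), and the lowest was 20. In replicate 1, 16665 genes had a median of 158, with 786 genes (4.72%) at the lowest value in each library. In replicate 2, 12455 genes had a median of 162.5, with 480 genes (3.85%) at the lowest value. Because quantile normalisation gives both libraries of a table the same total, the depth of a library is unknown, whole reads could not be recovered, and no counting interval is given. The 10 highest genes held 9.15% of the sum in each library of replicate 1 and 6.18% in replicate 2. The tables were normalised separately, so the test used differences within a table, and levels were set against each other between tables only in alternatives and in the check of the block. The number of genes differs between the tables, with 12242 in both, 4423 in replicate 1 only and 213 in replicate 2 only, and only genes in both tables entered the tests. Columns with per-sample values that were left unused numbered 0.

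Among 16878 gene identifiers, 16205 were found in a gene name table. The tables gave no symbol for 3039 identifiers, of which 2582 were named from it, and 20 symbols that a spreadsheet had turned into dates were restored. Symbols are otherwise those of the tables, some of them older ones, and 52 tested genes had no symbol. No genome of the build hg19 was used here, so gene positions are not given. The RefSeq gene table of another build served only for the order of neighbouring genes.

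Values were analysed as log2(value + 1) in R 4.3.3 with limma 3.58.1. Fold changes are on that scale and understate the change of genes near the lowest value. Genes with a mean of at least 40 over the 4 libraries (2 times the lowest value) were tested, 11159 in all. The linear model had the group and, as a block, the replicate, with variances moderated by eBayes with a trend on the mean level (prior degrees of freedom 13.0, residual degrees of freedom 1 per gene). The p-values are two-sided with Benjamini-Hochberg adjustment, and genes were called at an adjusted p under 0.05 with no fold minimum. The median SE was 0.158. An exact permutation test of 2 pairs cannot give a two-sided p below 0.5, so the calls rest on the spread pooled over genes.

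The block follows the authors' normalisation, which joined the libraries of a number. The labels do not say whether a number marks a shared day or culture, so it is not known whether the libraries of a number are paired beyond that normalisation. The fit without the block is an alternative.

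Gene lists, 29 in all, were fixed before the data were examined, as were the test and most alternatives. Of these lists 27 had at least 5 tested genes. They were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the 27 lists, and the calls within each list were also adjusted over the list alone. Camera at an estimated correlation and fry rest here on 1 residual degree of freedom per gene and so have little power. One list, of stable short noncoding RNAs, had 0 genes in both tables and was not tested. The genes named were MYC, the 12 largest rises and 12 largest falls among called genes with the same direction in both replicates, up to 4 called members of each list with the largest change, and the 5 tested genes with the highest mean. A few genes that this rule names are not reported here. PLK3 falls outside this rule and was named after its value was seen.

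The test was tested on simulated data for this comparison, with 11159 genes in 20 draws. With 200 changed genes it recovered 45.1% of those changed 1.5-fold, 85.3% at 2-fold, 98.9% at 3-fold and 99.5% at 4-fold, and the share of false calls had a median of 10.1% with a range of 1.97% to 24.1%. With 2999 changed genes of the sizes called it recovered 74.6%, with 4.72% false calls (3.66% to 6.69%). Those sizes are fitted folds of called genes, which selection may have enlarged, so recovery may be overstated. Noise was drawn independently for each gene and library from the variance prior of the same fit. The shares of false calls therefore check the model against its own assumptions. The fit without the block recovered 0% in both cases. That was largely built in, since each draw kept the observed difference between the tables, which that fit counts as noise. Alternatives changed the block, the pseudocount (0 and 20), the filter on low values, the scaling, the variance prior and the libraries used. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.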

Results

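Nascent transcription was measured by global run-on sequencing (GRO-seq) in U2OS cells, a human osteosarcoma cell line, that carried an inducible Myc expression vector. In this assay, engaged RNA polymerases in isolated nuclei extend their transcripts in the presence of bromo-UTP, and the labelled RNA is captured and sequenced. The value of a gene then reflects ongoing transcription rather than the store of mature RNA. Cells were induced for 5 hours or mock-treated, with 2 biological replicates per group per the labels' protocols, which gave 4 libraries. Whether mock-treated cells also received doxycycline, the inducer named in the protocols, is not stated in the labels. The comparison asks which genes were transcribed more or less after Myc induction. The values were gene read counts that the authors had quantile-normalised between the control and the Myc-induced library of a replicate and set to at least 20, as the deposited tables show. Both libraries of a replicate therefore held the same set of values, with a sum of 6267456 over 16665 genes in replicate 1 and of 3746367 over 12455 genes in replicate 2. The depth of each single library is unknown, and a change shared by all genes cannot be seen in these values. Rises and falls below are relative to the other genes of the library.

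MYC (ENSG00000136997), the induced transcription factor, had a value of 2526 in control replicate 1 and of 23213 in Myc-induced replicate 1. In replicate 2 it was 1612.5 in the control and 20656.5 after induction. The fitted change was 10.8-fold, a log2 fold change of 3.44 ± 0.13 (SE, n = 2 pairs; limma adjusted p = 2.91e-09), with log2 ratios of 3.20 and 3.68 in the 2 replicates. Transcripts of the vector and of the endogenous gene were not told apart. Among the partners and antagonists of MYC in the MYC-MAX network, MGA rose by 0.47 ± 0.10 on the log2 scale (adjusted p = 0.00497) and MXD3, a MAX dimerisation protein that competes with MYC, had a log2 fold change of -1.10 ± 0.14 (adjusted p = 0.000126). Of the 11 tested members of this list 2 rose, MYC included, and 1 fell, over all genes tested and adjusted over the list alone. As a group the list did not pass the test (median log2 fold change 0.21; camera adjusted p = 0.0662).

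Of 11159 genes tested, 1497 (13.4%) rose and 1502 (13.5%) fell after Myc induction at an adjusted p under 0.05, together 26.9% of the genes. Most of the changes were moderate. The median size among called genes was 0.65 on the log2 scale, 206 genes rose and 273 fell by over 2-fold, and 1192 called genes changed by less than 1.5-fold. Every called gene moved in the same direction in both replicates. The calling rule favours this, because ratios of opposite sign lower the mean and raise the residual spread of a gene. Without any variance model, 573 genes were over 1.5-fold higher and 659 over 1.5-fold lower in both replicates, against 7 that passed 1.5-fold in opposite directions. If the replicates were independent, 236 genes would be met in the same direction. Across genes, the log2 ratios of the 2 replicates correlated with a Pearson r of 0.73 and a Spearman rho of 0.68, a description only, since genes are not independent replicates.

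**Figure D1:**
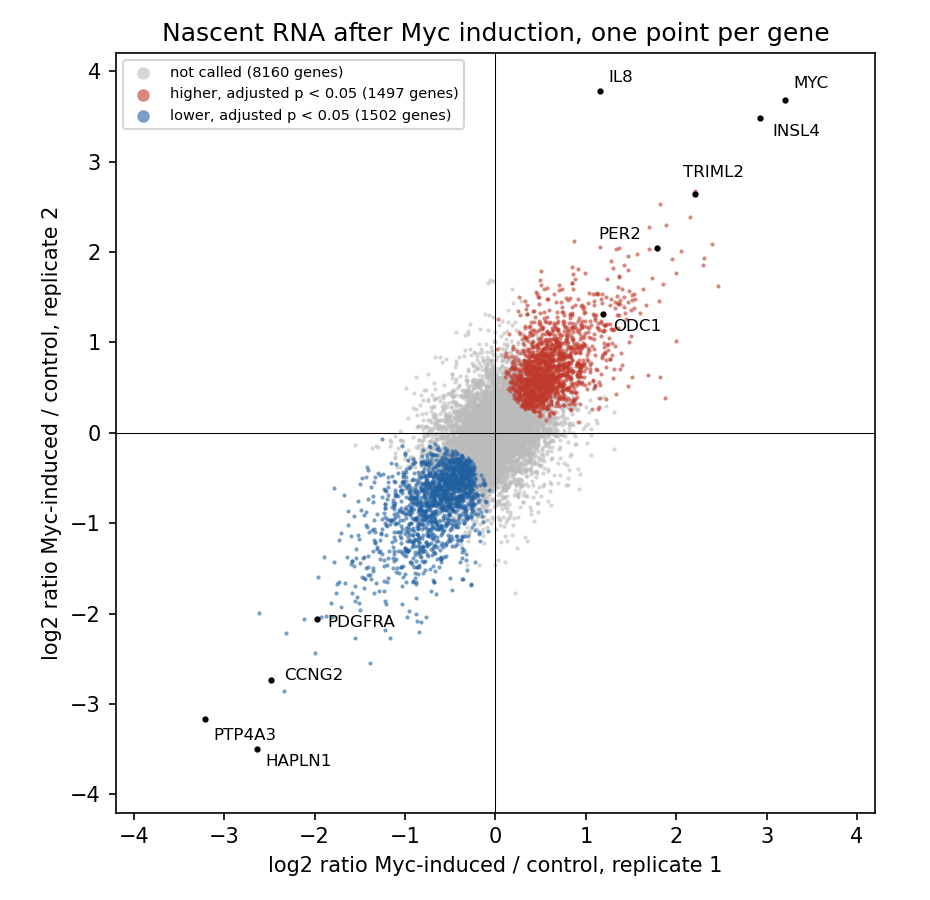
Log2 ratio of the Myc-induced to the control value in replicate 1 (horizontal axis) and replicate 2 (vertical axis), 1 point for each of the 11159 genes tested, with red points for the 1497 genes that rose, blue points for the 1502 that fell, grey points for the 8160 not called and black points for the genes named. Called genes lie in the upper right and lower left quadrants, with MYC at 3.20 and 3.68, while IL8 stands apart with 1.16 in replicate 1 and 3.79 in replicate 2.

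After MYC, the largest rise was that of INSL4 (ENSG00000120211), an insulin-like peptide known from the placenta, with a log2 fold change of 3.21 ± 0.24 (adjusted p = 2.41e-06). TRIML2 rose from 151 to 703.5 in replicate 1 and from 92 to 581 in replicate 2 (log2 fold change 2.43 ± 0.15, adjusted p = 5.04e-07). The inflammatory cytokine gene IL6 rose by 2.18 ± 0.21 on the log2 scale (adjusted p = 1.65e-05), with values of 81.5 and 46 in the controls and 290.5 and 271.5 after induction. The genes of the chemokine IL8 (CXCL8), the pseudokinase CAMKV and the orphan nuclear receptor NR4A3 stood at the lowest value, 20, in both controls, and against that value they were at least 5.76-fold, 4.91-fold and 4.42-fold higher after induction. For IL8 the replicates differed in size, with 46 in Myc-induced replicate 1 and 288.5 in Myc-induced replicate 2. IGFN1, MEGF11, PDZRN3, GALNTL1 and KRTAP2-3 completed the 12 largest rises, with log2 fold changes of 2.44, 2.27, 2.12, 2.08 and 2.04. All of these except GALNTL1 were at the lowest value in 1 control, so that their folds understate the rise. KRTAP2-3 belongs to a family of similar copies between which reads may have been split.

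The largest fall was that of PTP4A3 (ENSG00000184489), a protein tyrosine phosphatase of the PRL family, from 222 to 23 in replicate 1 and from 196 to 21 in replicate 2 (log2 fold change -3.19 ± 0.23, adjusted p = 2.41e-06). HAPLN1, a link protein that holds proteoglycans on hyaluronan, followed with -3.07 ± 0.22 (adjusted p = 2.41e-06). CCNG2, an atypical cyclin associated with cell cycle arrest, had a log2 fold change of -2.61 ± 0.15 (adjusted p = 2.66e-07), and C9orf84 one of -2.60 ± 0.13 (adjusted p = 3.89e-08). PDGFRA, a receptor for platelet-derived growth factor, stood at 441.5 and 467.5 in the controls and at 111.5 in both Myc-induced libraries (log2 fold change -2.02 ± 0.15, adjusted p = 2.41e-06). The cyclic GMP phosphodiesterase PDE5A (-2.26), the membrane-type metalloproteinase MMP24 (-2.22) and the laminin chain LAMA5 (-1.98) fell as well, as did JAKMIP2 (-2.30), OLFML2A (-1.97) and ZNF323 (-1.95). JAKMIP2 was at the lowest value in Myc-induced replicate 1. In Myc-induced replicate 2, PTP4A3 (21), MMP24 (21.5), OLFML2A (26) and HAPLN1 (27) were near it. The falls of these genes, and so their order, may be understated. Of all called genes, 5 that rose were at the lowest value in both controls and 2 that fell were at the lowest value in both Myc-induced libraries. Beyond those named above, these were MMP3 and SDIM1, at least 3.37-fold and 3.11-fold higher, and GPR162 and BMF, at least 3.51-fold and 3.21-fold lower, all 4 named after their values were seen.

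Genes for making ribosomes rose together. Among 58 tested genes of ribosome biogenesis and the nucleolus 45 rose and 0 fell, or 50 and 0 adjusted over the list alone. Their median log2 fold change was 0.61 (camera adjusted p = 2.74e-20; adjusted p = 0.501 with an estimated correlation). The estimated correlation between these genes, 0.129, was above the preset 0.01, so the p at the preset correlation may be too small. RRP9, a protein of the U3 small nucleolar ribonucleoprotein, rose by 1.56 ± 0.19, the ribosomal RNA processing factor RRP12 by 1.29 ± 0.14, the RNA helicase DDX10 by 0.98 ± 0.14 and the pseudouridine synthase PUS7 by 0.96 ± 0.13 on the log2 scale (adjusted p between 4.12e-05 and 0.000268). The machinery of RNA polymerase III, which transcribes 5S ribosomal RNA and transfer RNA, had 7 of 19 genes rising and 0 falling, the same counts adjusted over the list alone. Their median was 0.20 (camera adjusted p = 0.00552; adjusted p = 0.501 with an estimated correlation). Its leading members were the polymerase subunits POLR3K (0.87 ± 0.20) and POLR3G (0.71 ± 0.16) and the initiation factors GTF3A (0.87 ± 0.17) and GTF3C4 (0.57 ± 0.10). Translation factors also stood higher, with 10 of 20 rising and 0 falling, or 12 and 0 adjusted over the list alone (median 0.34, camera adjusted p = 8.17e-05; adjusted p = 0.501 with an estimated correlation). The largest rises were those of EIF1AX (0.61), EEF1E1 (0.54), EIF3B (0.54) and EIF3J (0.52).

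Genes of the ribosomal proteins themselves had a smaller median change. Among 75 tested genes of cytosolic ribosomal proteins 9 rose and 3 fell, or 3 and 0 adjusted over the list alone. The share that rose was no higher than the 13.4% of all tested genes that rose. The median was 0.17 (camera adjusted p = 0.0011; adjusted p = 0.501 with an estimated correlation). RPL8 (0.55 ± 0.12), RPL27 (0.51 ± 0.11) and RPL22 (0.49 ± 0.11) rose and RPL41 (-0.42 ± 0.12) fell. Many of these genes have processed pseudogenes with which reads may have been shared. Cytosolic aminoacyl-tRNA synthetases did not pass as a group (median 0.17, camera adjusted p = 0.065). HARS (0.62), IARS (0.50) and VARS (0.29) rose and 0 of 20 fell, or 2 rose and 0 fell adjusted over the list alone. The share of synthetases that rose was near the 13.4% of all tested genes. Chaperone genes rose as well. In the list of the cytosolic chaperonin and HSP90, 8 of 15 rose and 0 fell, or 11 and 0 adjusted over the list alone (median 0.32, camera adjusted p = 7.27e-05; adjusted p = 0.501 with an estimated correlation). They included HSP90AA1 (0.66), its co-chaperone AHSA1 (0.62), HSPA4 (0.55) and the chaperonin subunit TCP1 (0.49). Mitochondrial protein import and chaperones had 15 of 20 genes rising and 0 falling, or 16 and 0 adjusted over the list alone (median 0.51, camera adjusted p = 2.99e-07; adjusted p = 0.501 with an estimated correlation). PHB, a prohibitin of the inner membrane, rose by 0.94 ± 0.11, the chaperone TRAP1 by 0.83 ± 0.12, the mitochondrial RNA polymerase POLRMT by 0.79 ± 0.22 and the import subunit TIMM50 by 0.76 ± 0.18.

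Metabolic genes moved in both directions. In nucleotide biosynthesis 12 of 29 genes rose and 2 fell, the same counts adjusted over the list alone (median 0.21, camera adjusted p = 0.000669; adjusted p = 0.501 with an estimated correlation). DHODH, an enzyme of pyrimidine synthesis, rose from 261.5 to 570.5 in replicate 1 and from 115.5 to 340 in replicate 2 (log2 fold change 1.34 ± 0.15). IMPDH1, of guanine nucleotide synthesis, rose by 1.19 ± 0.17 and CTPS1 by 0.82 ± 0.10 on the log2 scale. NME1 (0.80) overlaps a read-through gene and is uncertain. For polyamine synthesis and amino acid uptake, 6 of 13 genes rose and 1 fell, or 6 and 2 adjusted over the list alone (median 0.16, camera adjusted p = 0.028; adjusted p = 0.501 with an estimated correlation). ODC1, the rate-limiting enzyme of polyamine synthesis, rose by 1.25 ± 0.10 (adjusted p = 4.55e-06) and spermidine synthase SRM by 1.00 ± 0.15. The amino acid transporters SLC7A5 and SLC7A1 rose by 0.75 ± 0.12 and 0.57 ± 0.12. Glycolysis had 7 of 21 genes rising and 2 falling, the same counts adjusted over the list alone (median 0.21, camera adjusted p = 0.0345; adjusted p = 0.501 with an estimated correlation). Hexokinase HK2 rose by 1.55 ± 0.13, the lactate transporter SLC16A1 by 0.85 ± 0.10 and PDK1 by 0.57 ± 0.16, and the enolase ENO2 had a log2 fold change of -1.04 ± 0.14.

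Cholesterol synthesis genes fell. Of 20 tested 0 rose and 15 fell, or 0 and 16 adjusted over the list alone. The median was -0.63 (camera adjusted p = 2.08e-08; adjusted p = 0.501 with an estimated correlation). Mevalonate kinase MVK fell from 268.5 to 122 in replicate 1 and from 198.5 to 70 in replicate 2 (log2 fold change -1.31 ± 0.18, adjusted p = 0.000279). The sterol-regulated gene INSIG1 changed by -1.06 ± 0.20, HSD17B7, at the lowest value in Myc-induced replicate 2, by -1.03 ± 0.26 and MSMO1 by -0.99 ± 0.12. The ATF4 and amino acid stress list was divided, with 3 of 17 rising and 3 falling, or 3 and 4 adjusted over the list alone (median -0.08, camera adjusted p = 0.604). TRIB3 (1.23) and CTH (0.81) rose, and NUPR1 (-1.22) and the serine synthesis enzyme PHGDH (-0.83) fell. In the lysosome and autophagy list 0 of 27 rose and 5 fell, the same counts adjusted over the list alone (median -0.10, camera adjusted p = 0.0982). The members that fell most were CTSB (-0.85), ULK1 (-0.81), NEU1 (-0.73) and MAP1LC3B (-0.56).

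**Figure D2:**
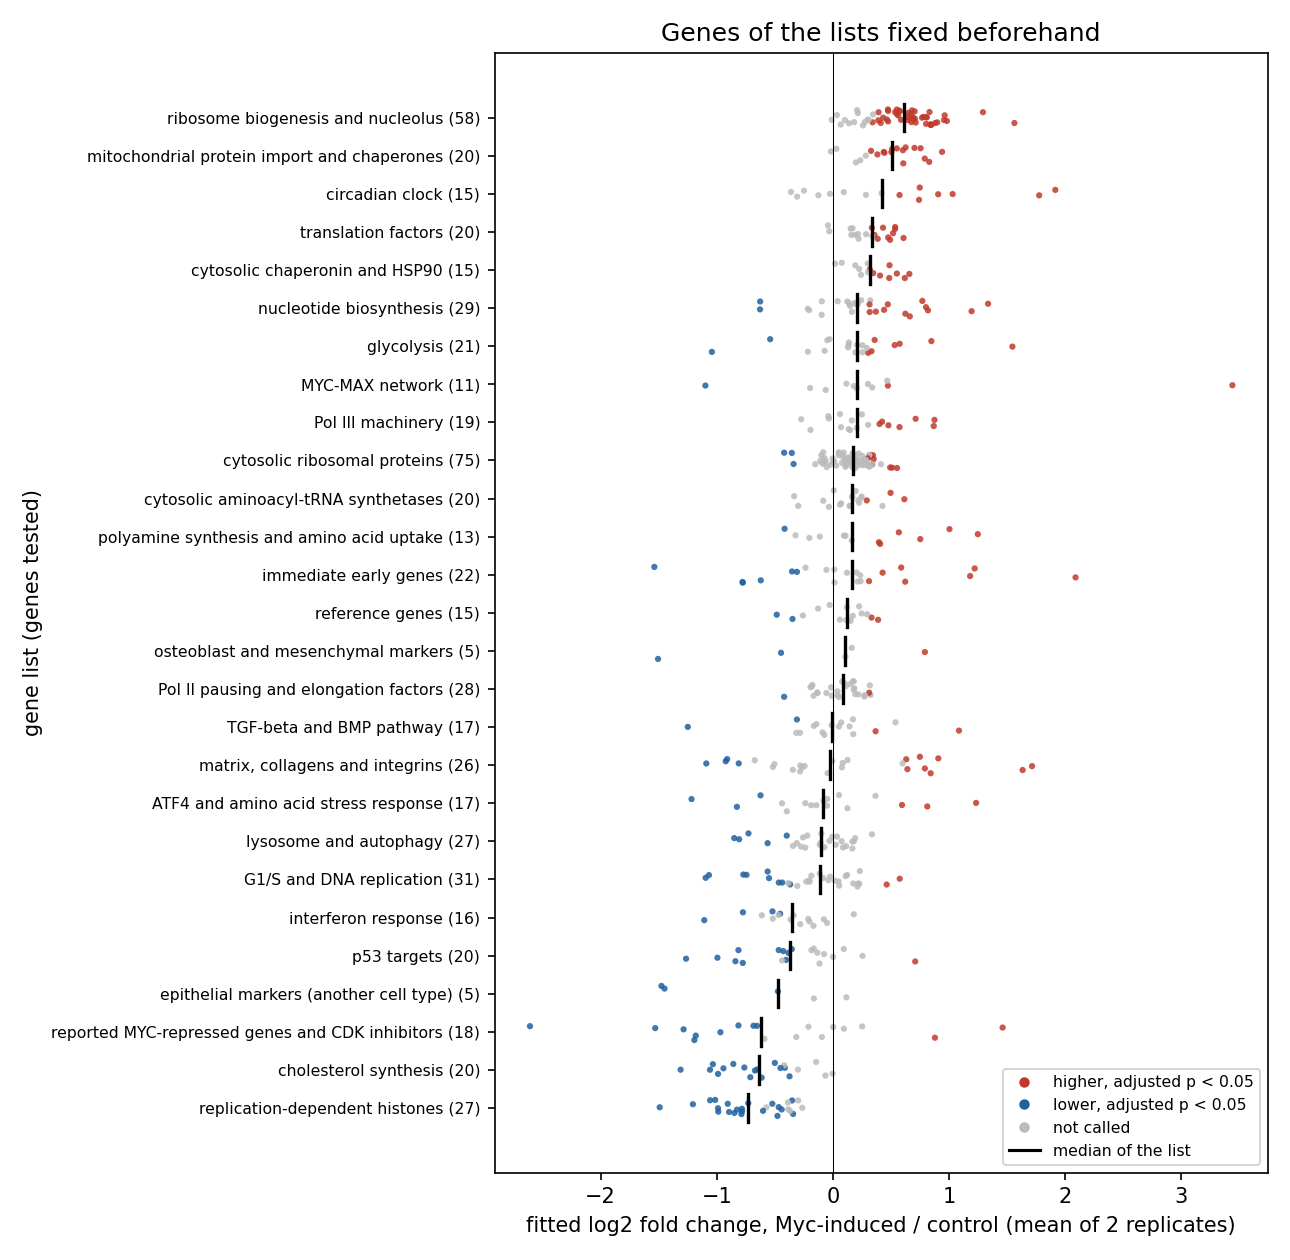
Fitted log2 fold change of Myc-induced over control (horizontal axis, mean of 2 replicates) for each tested gene of the 27 lists with at least 5 tested genes (vertical axis, number of genes in brackets), with red points for genes that rose, blue points for genes that fell, grey points for genes not called and a black bar for each list's median. The medians run from 0.61 for ribosome biogenesis to -0.73 for replication-dependent histones.

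Inhibitors of the cell cycle and other reported targets of MYC repression fell, with 9 of 18 falling and 2 rising, the same counts adjusted over the list alone (median -0.62, camera adjusted p = 0.000537; adjusted p = 0.501 with an estimated correlation). Besides CCNG2, the CDK4 and CDK6 inhibitor CDKN2C (-1.29 ± 0.19) and NDRG4 (-1.53 ± 0.16) fell, while the thioredoxin-binding protein gene TXNIP rose by 1.46 ± 0.17. Targets of p53 fell as well, with 10 of 20 falling and 1 rising, or 11 and 1 adjusted over the list alone (median -0.37, camera adjusted p = 0.00307; adjusted p = 0.501 with an estimated correlation). The CDK inhibitor CDKN1A, a member of both lists, stood at 1990 and 1715 in the controls and at 1306.5 and 845.5 after induction (log2 fold change -0.81 ± 0.11, adjusted p = 0.000279). TP53INP1 (-1.26), GDF15 (-0.99) and the pro-apoptotic gene BBC3 (-0.84) fell too, and PLK3 (0.71) rose. Genes of G1/S and DNA replication did not pass as a group (median -0.11, camera adjusted p = 0.0662). Of 31 tested 2 rose and 9 fell, the same counts adjusted over the list alone. The kinase CDK2 (-1.10 ± 0.15), the transcription factor E2F2 (-1.07 ± 0.13), the licensing factor CDT1 (-0.77 ± 0.14) and the helicase subunit MCM5 (-0.74 ± 0.11) were the largest falls.

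Replication-dependent histone genes, which are transcribed mainly in S phase, fell. Of 27 tested 21 fell and 0 rose, or 25 and 0 adjusted over the list alone (median -0.73, camera adjusted p = 5.76e-13; adjusted p = 0.517 with an estimated correlation). The estimated correlation between these genes, 0.85, was the highest of all lists tested and far above the preset 0.01. That estimate rests on 1 residual degree of freedom, but the p at the preset correlation may be far too small for this list. The list's median log2 ratio was -0.38 in replicate 1 and -0.94 in replicate 2. HIST1H1C had a log2 fold change of -1.49 ± 0.11 (adjusted p = 2.68e-06), HIST1H4A of -1.21 ± 0.15, HIST1H4I of -1.06 ± 0.13 and HIST1H2AK of -1.01 ± 0.20. Single histone genes are uncertain, since the copies are nearly identical and their reads may have been split between them.

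Clock genes were among those that rose. Of 15 tested circadian genes 7 rose and 0 fell, or 9 and 0 adjusted over the list alone (median 0.42, camera adjusted p = 0.0117; adjusted p = 0.501 with an estimated correlation). Among genes with a mean of at least 200 the call was lost, with a median of 0.13 over 8 circadian genes (adjusted p = 0.426). The period gene PER2 rose from 73 to 253.5 in replicate 1 and from 55.5 to 232.5 in replicate 2 (log2 fold change 1.91 ± 0.19, adjusted p = 2.6e-05). PER1 rose by 1.03 ± 0.15, the cryptochrome gene CRY1 by 0.91 ± 0.22, and HLF, at the lowest value in control replicate 2, by 1.78 ± 0.27. Immediate early genes divided, with 7 of 22 rising and 6 falling, the same counts adjusted over the list alone (median 0.16, camera adjusted p = 0.587). NR4A3, NR4A2 (1.18 ± 0.22) and the phosphatase gene DUSP2 (1.22 ± 0.14) rose. ZFP36, which encodes a protein that destabilises cytokine messages, had a log2 fold change of -1.54 ± 0.24. Interferon response genes fell, with 4 of 16 falling and 0 rising, the same counts adjusted over the list alone (median -0.35, camera adjusted p = 0.0037; adjusted p = 0.501 with an estimated correlation). Those 4 were PARP9 (-1.11), STAT2 (-0.77), DTX3L (-0.52) and IRF1 (-0.45).

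Matrix, collagen and integrin genes moved both ways. Of 26 tested 8 rose and 4 fell, or 9 and 6 adjusted over the list alone. The median was -0.02, the mean 0.07 and the test pointed up (camera adjusted p = 0.881). The tenascin gene TNC (1.71 ± 0.17) and the laminin chain LAMB1 (1.63 ± 0.15) rose, and the collagen V chains COL5A2 (-1.09 ± 0.22) and COL5A1 (-0.92 ± 0.22) fell. In the TGF-beta and BMP pathway 2 of 17 rose and 2 fell, the same counts adjusted over the list alone (median -0.01, camera adjusted p = 0.941). BMP2 (1.09) and ID1 (0.37) rose, and BMP4 (-1.25) and TGFB2 (-0.31) fell. BMP4 was at the lowest value in Myc-induced replicate 2. Among factors of RNA polymerase II pausing and elongation 1 of 28 rose, SSRP1 (0.31), and 1 fell, TOP2A (-0.42), or 0 and 1 adjusted over the list alone (median 0.09, camera adjusted p = 0.547).

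**Figure D3:**
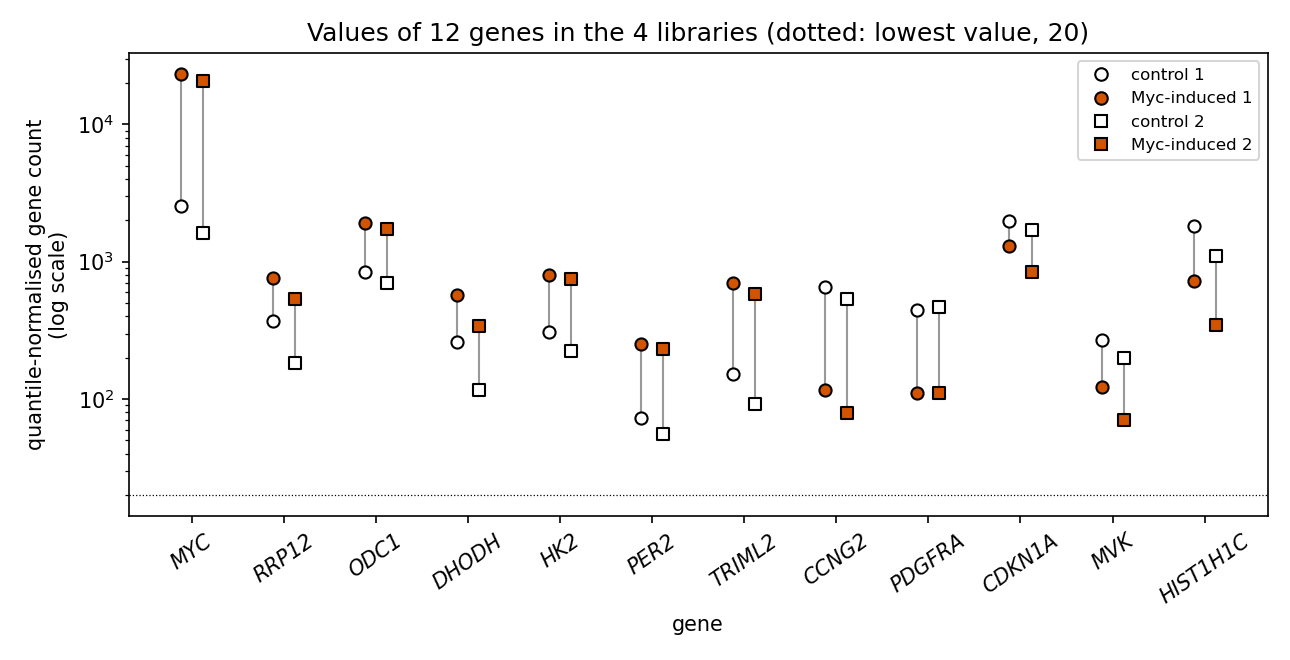
Quantile-normalised gene count (vertical axis, log scale) of 12 genes in control (open) and Myc-induced (filled) libraries, with circles for replicate 1, squares for replicate 2, a line joining the libraries of a replicate and a dotted line at the lowest value of 20. In both replicates MYC, RRP12, ODC1, DHODH, HK2, PER2 and TRIML2 are higher after induction and CCNG2, PDGFRA, CDKN1A, MVK and HIST1H1C are lower.

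Few markers of cell identity were tested, mainly because most were not in both tables, for reasons not known. Of 13 osteoblast and mesenchymal markers listed 6 were in both tables. Of 14 epithelial markers 5 were, and of 14 blood and endothelial markers 1 was. Of 5 tested osteoblast and mesenchymal markers 1 rose and 2 fell, the same counts adjusted over the list alone. Their median was 0.11, but the mean was -0.18 and the test pointed down (camera adjusted p = 0.587). The osteoblast transcription factor RUNX2 had a log2 fold change of -1.51 ± 0.23 and VIM of -0.45 ± 0.10, and PRRX1 rose by 0.79 ± 0.22. Among 5 tested epithelial markers 3 fell and 0 rose, the same counts adjusted over the list alone (median -0.47, camera adjusted p = 0.0167; adjusted p = 0.501 with an estimated correlation). EPCAM had 214 and 259 in the controls and 116.5 and 60.5 after induction (log2 fold change -1.48 ± 0.24), CLDN4 changed by -1.45 ± 0.16 and KRT8 by -0.47 ± 0.15. Only 1 of the blood and endothelial markers was tested, LCP1, with a log2 fold change of 0.54 ± 0.22 (adjusted p = 0.087). It was not called over all genes and was called, as 1 of 1, adjusted over the list alone. Of 15 reference genes often used for normalisation 2 rose, TUBA1B (0.39) and PGK1 (0.33), and 2 fell, among them TUBB (-0.48), the same counts adjusted over the list alone (median 0.12, camera adjusted p = 0.587). Both shares were near those of all tested genes, 13.4% rising and 13.5% falling.

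Among the genes tested, the 5 with the highest mean values were mitochondrially encoded, and none was called. Their log2 fold changes were 0.15 ± 0.20 for MT-ND6, 0.14 ± 0.18 for MT-CO1, 0.25 ± 0.18 for MT-ND5, 0.12 ± 0.16 for MT-ND4 and -0.03 ± 0.16 for MT-ND1. That of MT-CO1 became -0.06 when all 4 libraries were quantile-normalised together. In replicate 2, MT-ND6, MT-CO1, MT-ND5 and MT-ND4 held the same value in both libraries, as genes of equal rank do after quantile normalisation. Mitochondrially encoded genes took 8.32% of the summed values in control replicate 1 and 9.41% in Myc-induced replicate 1. In replicate 2 they took 6.19% in the control and 5.88% after induction. The shares of the 2 replicates rest on different genes and cannot be set against each other. For example, 15 mitochondrial transfer RNA genes with a mean of at least 40 were listed in replicate 1 alone.

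The calls came from limma with the replicate as a block, that is, from the ratios within each replicate, and 16 of the 27 lists passed camera with a preset correlation between genes, 10 upward and 6 downward. With no replicate block 0 genes were called by limma, with 865 at an unadjusted p under 0.05, and MYC, whose fitted log2 fold change the block cannot alter in this balanced design, had an adjusted p of 0.377. The calls of cytosolic ribosomal proteins (adjusted p = 0.0952) and glycolysis (adjusted p = 0.0914) were lost in that fit, in which the ribosomal protein median ran from -0.31 to 0.55 when single libraries were left out. With an estimated correlation or with fry, which both rest on 1 residual degree of freedom per gene, 0 lists passed. This loss says little about correlation between genes. Cholesterol synthesis, at an estimated correlation of -0.0105 against the preset 0.01, also went to a camera adjusted p of 0.501. Estimates were well above 0.01 for the cytosolic chaperonin and HSP90 (0.162), ribosome biogenesis (0.129), translation factors (0.116), p53 targets (0.116) and interferon response (0.083). For these lists, as for the histones (0.85), the p at the preset correlation may be too small. The other called lists had estimates of 0.0175 or below. Among genes with a mean of at least 200, 13 of the 16 calls stood, those of the circadian list and of glycolysis (adjusted p = 0.0889) were lost, and the epithelial list had too few genes to be tested.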

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

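Of the tests in this part, that on low mean value and the bound for other RNA polymerase III classes were chosen only after the result was seen. Apart from the random lists, which drew on all genes of the replicate 1 table at that mean or above, all values here come from genes listed in that table alone. These were 2468 genes with a mean of at least 40, which did not enter the comparison. Each value rests on 1 control and 1 Myc-induced library with no replicate check. Of these genes 114 were over 2-fold higher and 75 over 2-fold lower after induction. They were singled out because a signal above that of the control library appeared in data the comparison does not use.

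The long intergenic noncoding gene LINC00473 had the largest ratio, with 20, the lowest value, in the control and 223 after induction, a log2 ratio of 3.415 on the log2(value + 1) scale. LINC01060 followed with 92.5 and 913, a log2 ratio of 3.289. ENSG00000253256, a gene listed with no symbol, had 26 and 141, a log2 ratio of 2.395.

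Genes for 5S ribosomal RNA, nearly all annotated as pseudogenes, were higher in the Myc-induced library of replicate 1, with a median log2 ratio of 1.017 over 52 genes, 51 of them higher and 27 over 2-fold, and a summed value of 20907.5 in the control and 31671.5 after induction. The genes with the highest values, RNA5SP304 (8957.5 in the control) and RNA5SP199 (4491.5), had log2 ratios of only 0.368 and 0.441, and RNA5S9 had 0.679. The largest ratios were mostly those of genes with low control values. A low mean value was argued against as the source, since the median lay at percentile 100 of 10000 random lists matched on mean value, whose central 95% ran from -0.151 to 0.157. The genes of those lists are unrelated, whereas 5S copies can share reads and move together, so that range may be too narrow for them. A gain of all short noncoding RNA in that library was argued against as the whole cause, since 93 small nucleolar, Cajal body and microRNA genes had a median of 0.284 (bootstrap interval 0.179 to 0.399), though that is itself at percentile 100 of their matched lists. The summed value of those 93 genes was 50007.5 in the control and 49336 after induction. Where such genes overlap longer genes they can share reads with them, so their values may not reflect short RNA alone. Other RNA polymerase III classes were represented by 23 genes, chosen by the names RNU6, RN7SK, RN7SL, RNY, VTRNA, RMRP and RPPH1. Their summed value was 14642 in the control and 14424.5 after induction. Their median was 0.078 (bootstrap interval 0.0136 to 0.277). On the same grounds this argued against a gain shared by these classes as the whole cause. The bound set beforehand, a median at or below 0, was not met. Nuclear transfer RNA genes were not among them, so a gain shared with those genes was not examined. Reads shared between the copies may move single genes or the class together, an effect of Myc induction on 5S transcription stays an untested hypothesis, and 1 library per group cannot separate it from a difference of that library.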

How the results depend on the processing

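Tests of the loss of calls without the block, and 3 alternatives (joint quantile normalisation with no replicate block, genes above the lowest value in all 4 libraries, removal of mitochondrially encoded genes), were chosen only after the result was seen. The count of genes changed by Myc induction, 2999, lay between 2755 and 3153 with a pseudocount of 0 or 20, no filter on low values, median centring, joint quantile normalisation, a robust prior, genes above the lowest value and removal of mitochondrial genes. It was 1925 at a mean of at least 200, where 6135 genes were tested, and 1809 without a variance trend, for which the cause was not tested. With no replicate block it was 0 (865 at an unadjusted p under 0.05, MYC 3.439 with an adjusted p of 0.377), and 1 with joint quantile normalisation added (1875). Leaving out single libraries in that unpaired fit, with the lone library assumed to vary like the others, gave 28 calls without control replicate 1, 7 without Myc-induced replicate 1, 45 without control replicate 2 and 0 without Myc-induced replicate 2, and a MYC log2 fold change of 3.115 to 3.763. With either replicate alone there is no test, and every called gene among the 129 named had the direction of the fit in both. The rules for calling and naming genes favour that agreement, so it is no separate check. Of those not called, MT-ND1 turned to 0.14 with replicate 1 alone, and MT-ND6, MT-CO1, MT-ND5 and MT-ND4 were at 0 with replicate 2 alone. Every call among the named genes was lost with no replicate block, 27 without a variance trend, 3 with joint quantile normalisation and 2 with no filter. The count over 1.5-fold in both replicates, 1232, was 244 at 2-fold and 463 at a mean of at least 200. The fit without the block counts differences between the tables as noise. These differences were largely shared by both libraries of a replicate, since they correlated across genes (r = 0.73). The ratio of opposite to same-direction genes was 0.00568. Effects of opposite direction count as noise in both fits, so this ratio cannot decide why calls were lost.

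Of the 16 lists called, 0 passed with an estimated correlation and 0 with fry, both of which rest on 1 residual degree of freedom. For that reason both have little power. Without the block 14 lists passed, with cytosolic ribosomal proteins (adjusted p = 0.0952) and glycolysis (0.0914) lost, and 10 to 15 when single libraries were left out of that fit. At a mean of at least 200, 14 of 25 lists passed, 13 of them among the 16, with the circadian list (median 0.1296 over 8 genes, adjusted p = 0.426) and glycolysis (0.0889) lost, epithelial markers too few to be tested, and lysosome and autophagy genes gained (adjusted p = 0.0355). With joint quantile normalisation and no replicate block 18 lists passed, the MYC-MAX network and the aminoacyl-tRNA synthetases gained (adjusted p = 0.0474 for each). In lists not called, the direction of the test turned for the TGF-beta and BMP list with no replicate block (median -0.01125), with joint quantile normalisation added (-0.00252) and above the lowest value (0.02038), for immediate early genes at a mean of at least 200 (0.01367), for the matrix list above the lowest value (-0.04525) and for the ATF4 list with fry (-0.08183); the cause was not tested. MT-CO1 turned to -0.0634 with joint quantile normalisation, with or without the block.

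In the unpaired fit, leaving out single libraries turned the direction of some results, since 1 library then stands against 2 across the tables. The log2 fold changes ran from -0.1516 to 1.888 for GTF3A, -0.1959 to 1.267 for EIF3B, -0.1908 to 1.296 for RPL8, -0.4563 to 1.443 for RPL22, -0.696 to 0.07635 for TGFB2, -0.9119 to 0.00344 for IRF1, -0.2488 to 0.8727 for SSRP1 and -0.1816 to 0.9595 for TUBA1B. They ran from -0.01548 to 0.3073 for MT-ND6, -0.1422 to 0.4245 for MT-CO1, -0.1864 to 0.6828 for MT-ND5, -0.1942 to 0.4325 for MT-ND4 and -0.3617 to 0.2962 for MT-ND1. List medians ran from -0.3134 to 0.5469 for cytosolic ribosomal proteins, -0.2525 to 0.2359 for matrix, -0.3204 to 0.2923 for TGF-beta and BMP, -0.102 to 0.3924 for immediate early genes and -0.4252 to 0.2034 for ATF4. The alternative that takes the median over entries of a symbol was not run, since 0 tested symbols had several, nor were count models, since whole reads could not be recovered. The depth of each library is unknown, and folds are lower bounds where both libraries of a group stand at the lowest value.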

Other observations

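Of the content of this part, the G2/M and inflammatory lists and the test on replication-independent histones were chosen only after the result was seen. Of 48 tested genes of the G2 and M phases 22 fell and 0 rose, beside 13.5% of all tested genes that fell, and the others were not called. Their median log2 fold change was -0.28 (interval -0.397 to -0.204 by a bootstrap over genes), and the list as a whole was not tested. CDC25C, a phosphatase that triggers mitosis, had a log2 fold change of -0.77 (adjusted p = 0.00884), CDCA3 of -0.75, CKAP2L of -0.70, HMGB2 of -0.68 and the proliferation marker MKI67 of -0.53 (adjusted p = 0.00265), while the kinase gene PLK1 (0.29, adjusted p = 0.0729), RANGAP1 (0.24), KIF23 (0.02) and CKAP5 (0.01) were not called. In a list of inflammatory genes drawn up after IL6 and IL8 were seen among the largest rises, IL11 (0.71, adjusted p = 0.043) and NFKBIZ (0.66, adjusted p = 0.00106) also rose, and ICAM1 (0.32), CCL2 (0.18), NFKBIA (0.14), TNFAIP3 (0.10), CSF1 (0.08) and LIF (-0.11) were not called. The long nuclear RNA genes NEAT1 and MALAT1, in the replicate 1 table alone, went from 59631.5 to 35932 and from 23213 to 13333, with no replicate check.

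The fall of replication-dependent histone genes was set against 3 explanations. Reads moved among the 35 measured histone cluster genes were argued against as the whole cause, since their summed value fell in both tables, with log2 ratios of -0.4666 and -0.957. Reads moved to copies outside these 35 genes, or left uncounted, would also lower the sum and were not examined. A fall of all histone genes stays open, since 6 of 10 tested replication-independent histone genes fell and 0 rose, with a median of -0.4036 (interval -0.634 to -0.124). H1F0 (-1.44) fell most, while H3F3A (-0.11), H3F3B (-0.14), CENPA (-0.14) and H2AFY (-0.09) were not called. Fewer cells in S phase stays open, since 27 further G1/S and S phase genes had a median of -0.2162 (interval -0.351 to -0.0922), neither near 0 nor as low as the histones. An effect of Myc on histone transcription itself is a hypothesis that these data do not separate from a change in cell cycle stages.

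Neighbouring genes may change together. Adjacent here means next to each other among the 10129 tested genes that could be placed on a chromosome. Other genes between them were skipped and no limit on distance was set. Of 739 pairs of adjacent called genes whose names differ in the first letters, 430 (58.19%) moved in the same direction, against a central 95% of 46.4% to 53.6% in 10000 permutations of the directions (two-sided p = 2e-04, the smallest they can give). Read-through transcription and overlapping genes counted without regard to strand remain untested sources of that excess.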
